A study of Arabidopsis thaliana with 27 samples.

How the data were processed

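Per the labels' protocols, root RNA was extracted with Trizol, treated with DNase and made into libraries with the TruSeq RNA kit v2. This kit does not mark the strand, so reads of a gene and of an antisense partner cannot be told apart. The labels also state that all samples were collected at the same time. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq 0.6.1, DESeq2 1.18.1 and the TAIR10 genome were used, with no role or order given. How reads that map to several genes were treated is not given in the sources used here, so genes with near-identical copies (the S30 genes, PER34 and PER33, the CAB and RBCS families, IGMT1 and IGMT2, AOC genes, ORG2 and ORG3, tandem GSTU and MSRB genes) are uncertain.

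The authors deposited, per the file headers, a table of normalized counts with the libraries of a group packed in 1 cell, together with log2 fold changes, p-values and adjusted p-values of their own comparisons and the authors' gene lists. The deposited values are counts divided by a size factor per library: multiplied back, 100% of values in every library came out whole within 0.1 reads. At the depth given by the recovered totals, 3 reads correspond to 0.154 to 0.316 CPM, counts scaled to library size. Such floors cover counting error only. Of 34262 genes, 6121 had no reads. Positions are those of the deposited table, and 99.969% of 32536 genes of the reference annotation start at the same base.

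Libraries were placed in 9 groups by label name, with replicate numbers. Replicate 5 of ICT1-2_NT was not analysed here because no column carries its name. No libraries were the same within sampling noise, and Spearman correlations within a group were at least 0.962. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

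Before the data were examined, a quasi-likelihood test on raw counts had been planned. Since the table holds normalized counts, the test was limma 3.58.1 (R 4.3.3) on log2(normalized count + 1), over genes with at least 10 normalized counts in at least 3 libraries (21180 genes). All 26 libraries entered a single fit with a mean per group and a variance trend (eBayes), comparisons and interactions were contrasts of group means, and genes passed at an adjusted p under 0.05 (Benjamini-Hochberg, two-sided). Fold changes are on the log2(value + 1) scale, which understates the change of genes with low counts, and no fold is given for a gene at 0 in all libraries of a group. Alternatives fixed before the data were examined were other filters on low counts (none, or at least 5 CPM in 3 libraries), fits of the compared groups alone, the replicate number as a block, an absolute log2 fold change over 1, and leaving out each library in turn. Alternatives added after seeing the data were scaling by TMM (the exchange of scalings planned before, turned round) or total reads, pseudocounts of 0.5 and 5, replicate numbers 4 and 5 against the others as a block, voom on the recovered reads, the calls in the authors' deposited table, and list tests without ICT1-8098_200 replicate 2.

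Gene lists were fixed before the data were examined: 26 lists with 421 genes, all in the table, which cover S30, auxin response, tryptophan and auxin synthesis, indole and aliphatic glucosinolate synthesis, glucosinolate breakdown and ER bodies, camalexin, xenobiotic detoxification, oxidative stress, heat shock, the unfolded protein response, jasmonate, salicylate, ethylene, abscisic acid, cell cycle, DNA damage, autophagy, sulfur and iron deficiency, the circadian clock, and markers of shoot photosynthesis, root hairs, endodermis and suberin, vasculature, and root meristem and cap. Ribosomal proteins were added by a rule on the annotation, which lets in some proteins of organelles. The 27 lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The test with an estimated correlation is given beside each call. Calls that held with it were those of heat shock and detoxification genes in every I3C response, sulfur deficiency genes in ICT1-2 at 200 µM, abscisic acid genes in ICT1-8098, and jasmonate, oxidative stress, glucosinolate breakdown, and tryptophan and auxin synthesis genes after wounding.

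The rule for naming genes was also fixed in advance: the S30 genes in every group, the 6 largest rises and 6 largest falls per comparison among genes that passed, had a mean of at least 5 CPM and did not overlap between groups (a condition left out for interactions), up to 4 passing members of each list with the largest change or else the 2 with the highest level, and the 6 genes called the same way in both lines and with I3C in Col-0 that had the smallest adjusted p-values. The last part was read as both I3C doses after the data were seen. Where comparisons shared a control group, overlaps and correlations were set beside 20 simulations of unchanged groups and beside the number expected of independent lists. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

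The test was tried on simulated data with 200 genes changed, so rates may differ where far more change. For Col_200 against Col_NT (20791 genes in the fit), 14.1%, 57.3% and 82.0% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. For ICT1-2_NT against Col_NT (20834 genes) the shares were 23.5%, 50.8% and 84.6%, and for the interaction of ICT1-2 and 200 µM I3C (20802 genes) 4.41%, 26.2% and 73.1%, none in the wrong direction. Of the calls, 5.56%, 4.55% and 2.82% were false. The list test, on Col_200 against Col_NT (21180 genes), called 3 of 3 lists shifted 2-fold or 1.5-fold and 1 of 3 shifted 1.2-fold. It also called 1 unshifted list. These runs do not test the preset correlation on real lists.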

Results

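RNA was sequenced from roots of 10-day-old Arabidopsis thaliana seedlings of 3 homozygous lines grown hydroponically. Col-0 was the wild type. ICT1-2, which carries a transgene made by the submitters, and ICT1-8098, which comes from an overexpression library of full-length cDNAs (FOX), are both labelled as overexpressing ribosomal protein S30 from the 35S promoter. Sets of 20 seedlings were kept for 2 h in DMSO or in indole-3-carbinol (I3C), a breakdown product of indole glucosinolates, at 200 or 400 µM. In a separate Col-0 group each leaf was wounded 3 times and roots were taken after 8 h. The 9 groups are named by line and treatment: Col_NT, Col_200, Col_400 and Col_w (wounded), ICT1-2_NT, ICT1-2_200 and ICT1-2_400, and ICT1-8098_NT and ICT1-8098_200. Each group had 3 libraries except ICT1-2_NT, for which 2 were analysed here, so 26 of the 27 libraries of the series entered the comparisons. Total reads assigned to genes ran from 9503924 in Col_200 replicate 4 to 19433428 in ICT1-2_400 replicate 3, with a median of 14169035.5. Of 34262 genes, 28141 had reads and 21180 passed the filter on low counts. Levels are means of normalized read counts ± SD, n = 3 unless the group is ICT1-2_NT (n = 2), and adjusted p-values are from limma with Benjamini-Hochberg adjustment. Counts of list members are over all tested genes, and the count adjusted over the list alone is added where it differs.

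The first question was whether the 2 lines had more S30 transcript than Col-0. Arabidopsis has 3 genes for this protein of the small ribosomal subunit. RPS30A (AT2G19750, chromosome 2, 8514899 to 8516138, TAIR10) was at 2659 ± 728 normalized counts in Col_NT and at 5743 ± 821 in ICT1-8098_NT (log2 fold change 1.14, SE 0.21, adjusted p = 0.000649). In the libraries labelled ICT1-2_NT it was at 2429 ± 540 (log2 fold change -0.11, SE 0.24, adjusted p = 0.796). With 200 µM I3C, RPS30A was at 2862 ± 151 in Col-0, 8303 ± 486 in ICT1-8098 (1.54, SE 0.21, adjusted p = 1.32e-05 against Col_200) and 2551 ± 565 in ICT1-2 (adjusted p = 0.575), and with 400 µM it was at 2313 ± 633 in Col-0 and 2149 ± 88.8 in ICT1-2 (adjusted p = 0.838). Wounded Col-0 roots had 2948 ± 817. The copy AT4G29390 (chromosome 4, 14464856 to 14466029) was at 1183 ± 126 in Col_NT, 958 ± 125 in ICT1-2_NT (adjusted p = 0.319) and 889 ± 119 in ICT1-8098_NT (adjusted p = 0.148). The copy AT5G56670 (chromosome 5, 22935211 to 22936084) was at 6089 ± 338, 5787 ± 751 (adjusted p = 0.833) and 5531 ± 523 (adjusted p = 0.697). With 200 µM I3C both copies lay lower than in Col_200 in both lines, and passed in ICT1-8098. There AT4G29390 was at 852 ± 211 against 1416 ± 386 in Col_200 (-0.72, SE 0.18, adjusted p = 0.00555, or 0.133 with only these groups in the fit), and AT5G56670 changed by -0.52 (adjusted p = 0.0327), a call lost with only these groups (0.241), under total-read scaling (0.126) and without Col_200 replicate 4 or 5 (0.122 and 0.198) or ICT1-8098_200 replicate 2 or 3 (0.148 and 0.0895). In ICT1-2 they changed by -0.40 and -0.42 (adjusted p = 0.121 and 0.0914), or -0.65 and -0.66 without Col_200 replicate 1 (0.0061 and 0.00394). Without that library both also passed as higher in Col_200 than in Col_NT (0.47 and 0.56, adjusted p = 0.0295 and 0.00894, against 0.381 and 0.188 with it). A rise of an S30 gene was measured for ICT1-8098 and not for the libraries labelled ICT1-2, so comparisons of ICT1-2 are named by its label. Reads of near-identical copies may have been split between the 3 genes, and summed over them the log2 change was -0.11 in ICT1-2_NT (95% interval -0.46 to 0.23) and 0.29 in ICT1-8098_NT (-0.018 to 0.60).

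**Figure D1:**
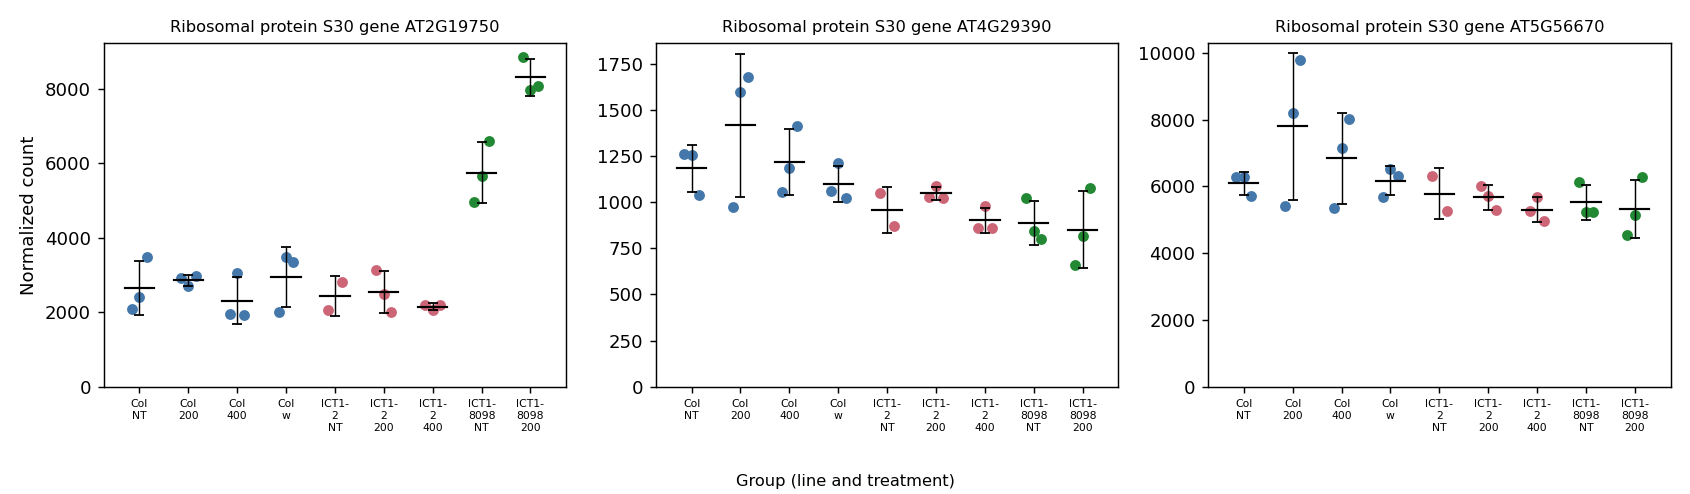
Normalized read counts (vertical axes) of the 3 ribosomal protein S30 genes in each of the 26 libraries, by group, with the mean and SD of each group. RPS30A lies higher in the ICT1-8098 libraries (5743 ± 821 without I3C) than in the Col-0 libraries (2659 ± 728), and the libraries labelled ICT1-2 lie at 2429 ± 540.

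I3C at 200 µM against DMSO in Col-0 asked which root transcripts respond within 2 h. 6120 of 21180 genes passed, 3181 higher and 2939 lower. Small heat shock proteins were among the largest rises. HSP23.6 (AT4G25200, chromosome 4, 12916926 to 12918110), of mitochondria, rose from 0.86 ± 0.881 to 13490 ± 4280 (log2 fold change 12.90, SE 0.61, adjusted p = 1.18e-13), and HSP22.0, of the endoplasmic reticulum, from 1.65 ± 0.105 to 7856 ± 1360 (11.52, adjusted p = 2.69e-14). The cytosolic HSP17.6A, HSP17.4 and HSP17.6II rose by 10.88, 10.63 and 10.32 on the log2 scale, and the DnaJ protein gene AT1G71000 by 10.54. Among the largest falls were SLAH1, an anion channel homologue (954 ± 429 to 18.4 ± 31.8, log2 fold change -7.84), the peroxidase gene PER59 (4003 ± 337 to 58.7 ± 42.7, -6.49), AT3G01260 (-5.88) and AT5G19970 (-5.50). The share of called genes that were higher was 52.0%, or 23.4% when libraries were scaled by total reads, a scaling that moved the median log2 fold change of all genes from -0.03 to -0.33.

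All 21 heat shock and protein folding genes rose with 200 µM I3C (camera adjusted p = 2.54e-40, or 0.00391 with estimated correlation). The 36 xenobiotic detoxification genes had 30 up and 0 down, or 31 up and 0 down over the list alone (camera adjusted p = 2.78e-28, or 0.00212 with estimated correlation). Among them were the glutathione transferase GSTU5 (40.2 ± 2.88 to 5753 ± 763, log2 fold change 7.12, SE 0.31, adjusted p = 3.9e-14), UGT74E2, a glucosyltransferase that acts on indole-3-butyric acid (5.51, SE 0.61), and the oxophytodienoate reductase homologue OPR1 (5.03, SE 0.23). The aldo-keto reductase gene AKR4C9 went from 0 ± 0 to 39.7 ± 7.26 (adjusted p = 6.83e-08). The oxidative stress list had 10 up and 2 down of 18, or 11 up and 2 down over the list alone (camera adjusted p = 0.000663, or 0.1 with estimated correlation). Rises included those of the ascorbate peroxidase APX2 (6.07, SE 0.59, adjusted p = 2.73e-08), the zinc finger protein ZAT12 (3.99) and the alternative oxidase AOX1A (226 ± 50.7 to 2350 ± 708, 3.35). The sulfur deficiency list had 11 up and 1 down of 13 (camera adjusted p = 1.01e-08, or 0.1 with estimated correlation). LSU1 rose from 18.7 ± 7.68 to 830 ± 45.1 (5.47, SE 0.42, adjusted p = 6.13e-10), as did LSU2 (4.14) and SDI1 (4.05), a repressor of glucosinolate synthesis. The abscisic acid and drought list had 14 up and 1 down of 20, or 15 up and 1 down over the list alone (camera adjusted p = 1.78e-06, or 0.1 with estimated correlation). The protein phosphatases HAI3 (5.42, SE 0.76, adjusted p = 5.78e-06) and HAI1 (4.09) rose, as did NCED3, which catalyses the rate-limiting step of abscisic acid synthesis (192 ± 132 to 1618 ± 413, 3.40).

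The aliphatic branch of glucosinolate synthesis had 0 up and 12 down of 14 (camera adjusted p = 4.24e-11, or 0.117 with estimated correlation). BAT5, a plastid transporter of this pathway, fell from 1002 ± 200 to 81.9 ± 82.6 (log2 fold change -4.19, SE 0.60, adjusted p = 8.67e-06), as did the cytochrome P450 CYP79F2 (-4.16), the aminotransferase BCAT4 (-3.85) and the chain-elongating MAM1 (-3.81). The indole branch had 3 up and 8 down of 18 (camera adjusted p = 0.0403, or 0.715 with estimated correlation). Falls included those of CYP79B3, which converts tryptophan to indole-3-acetaldoxime (2046 ± 302 to 564 ± 114, -1.87), the lyase SUR1 (-1.59) and the regulator MYB34 (-1.54), while the methyltransferase IGMT2 rose (2.22, SE 0.58, adjusted p = 0.00547). The camalexin and related indole list had 6 up and 0 down of 8, or 7 up and 0 down over the list alone (camera adjusted p = 6.12e-05, or 0.24 with estimated correlation). Among them were the transporter ABCG40 (55 ± 9.43 to 18960 ± 7370, 8.35), PAD3, which makes camalexin (2.57), and CYP71A12 (2.28). The iron deficiency list had 0 up and 8 down of 14, or 0 up and 9 down over the list alone (camera adjusted p = 8.71e-05, or 0.24 with estimated correlation). Falls included those of BHLH100 (-4.80, SE 0.76, adjusted p = 2.95e-05), MYB10 (-4.16) and the ferric reductase FRO2 (2556 ± 1080 to 268 ± 133, -3.29). Root hair markers had 0 up and 3 down of 7 (camera adjusted p = 0.0291, or 0.691 with estimated correlation), and of ribosomal proteins 22 rose and 2 fell of 297, with a median log2 fold change of 0.26 that became -0.05 under total-read scaling, with 3 up and 13 down (camera adjusted p = 6.12e-05, or 0.766 with estimated correlation).

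The remaining lists did not pass camera with 200 µM I3C, although single members did. Of the hormone lists, auxin response had 8 up and 4 down of 28 (adjusted p = 0.266). Tryptophan and auxin synthesis had 0 up and 4 down of 17 (adjusted p = 0.261). Jasmonate and wound response had 5 up and 2 down of 22 (6 up and 3 down over the list alone, camera adjusted p = 0.62). Salicylate and pathogen defence had 4 up and 0 down of 15 (adjusted p = 0.542). Ethylene synthesis and response had 5 up and 5 down of 15 (8 up and 5 down over the list alone, camera adjusted p = 0.625). Here GH3.3, which conjugates auxin, rose by 3.17, SE 0.44, adjusted p = 4.82e-06, the ACC synthase ACS7 by 5.33 and the glutaredoxin GRX480 by 3.03. Of the cell function lists, unfolded protein response had 3 up and 1 down of 11 (adjusted p = 0.103). Cell cycle had 0 up and 0 down of 23 (adjusted p = 0.953). DNA damage response had 1 up and 0 down of 11 (adjusted p = 0.96). Autophagy had 6 up and 3 down of 22 (adjusted p = 0.205). Circadian clock had 3 up and 2 down of 12 (adjusted p = 0.448). The J protein ERDJ3A of the endoplasmic reticulum rose by 7.67, SE 0.28, adjusted p = 1.83e-15, the autophagy protein ATG18A by 1.69 and the clock regulator CCA1 by 4.16. Of the markers and remaining lists, shoot photosynthesis markers had 0 up and 0 down of 14 (adjusted p = 0.156). Endodermis and suberin markers had 2 up and 1 down of 13 (adjusted p = 0.777). Vascular markers had 0 up and 3 down of 9 (adjusted p = 0.0597). Root meristem and cap markers had 0 up and 0 down of 6 (adjusted p = 0.858). Glucosinolate breakdown and ER bodies had 2 up and 2 down of 10 (adjusted p = 0.674). Ribosomal protein S30 genes had 0 up and 0 down of 3 (adjusted p = 0.589). Under total-read scaling the balance of calls turned for salicylate (1 up and 5 down), jasmonate (2 up and 4 down), unfolded protein response (2 up and 4 down), clock (2 up and 4 down), DNA damage (1 up and 2 down) and suberin genes (2 up and 6 down). Auxin and autophagy genes had 5 up and 5 down and 4 up and 4 down, and cell cycle genes 0 up and 7 down. PHO1, a phosphate exporter of the root stele, fell from 9555 ± 2980 to 1291 ± 436 (-2.90, SE 0.21, adjusted p = 3.06e-10).

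**Figure D2:**
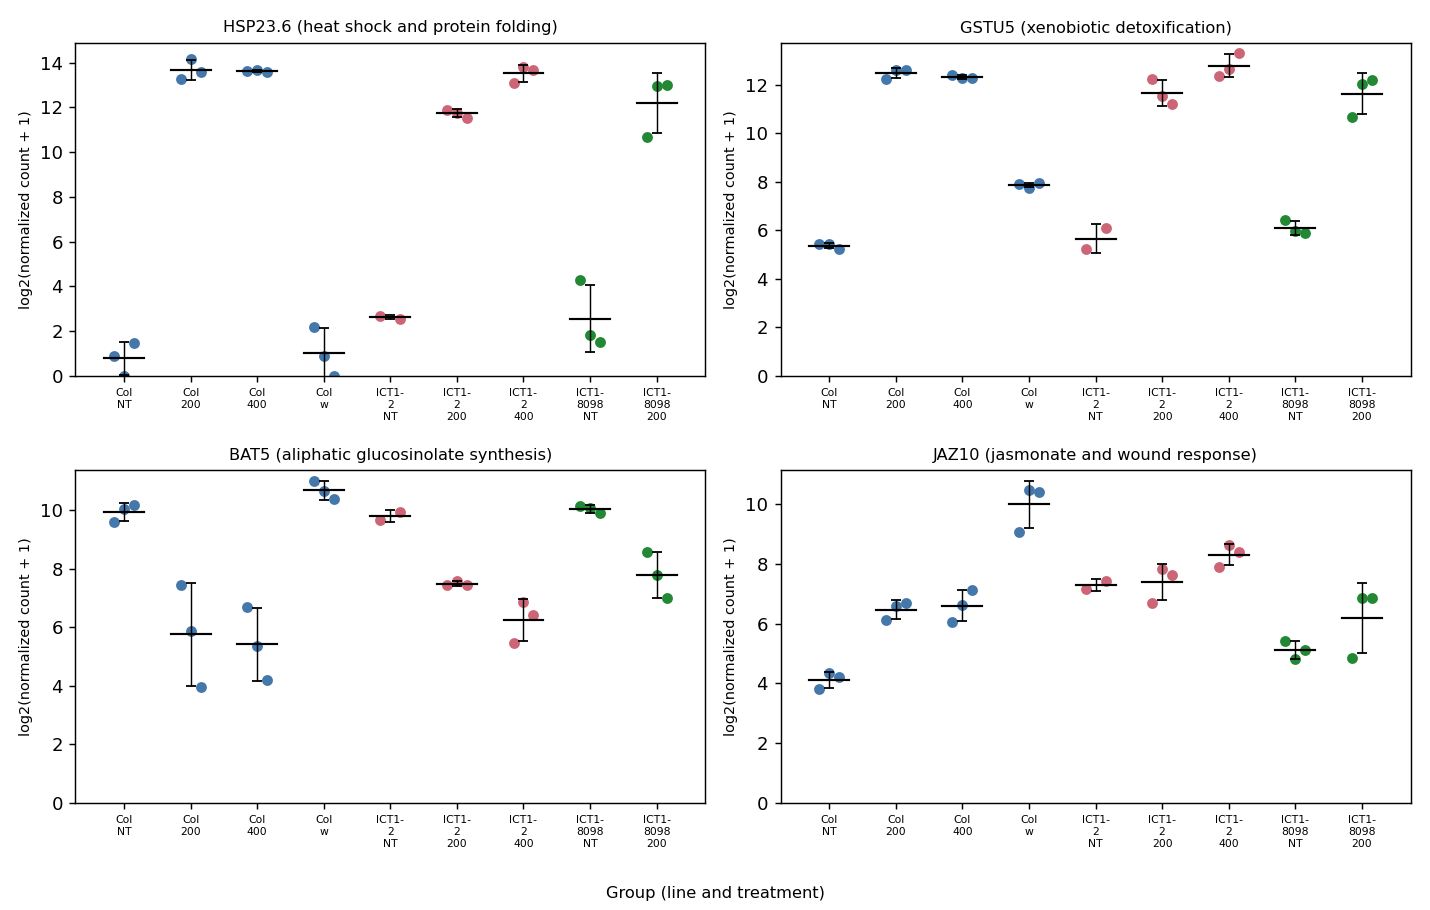
Levels of HSP23.6, GSTU5, BAT5 and JAZ10 in each library, as log2(normalized count + 1) on the vertical axes, with the mean and SD of each of the 9 groups. HSP23.6 and GSTU5 lie higher and BAT5 lower in the I3C groups of every line than in the same line without I3C, and JAZ10 lies higher in wounded than in unwounded Col-0 (16.7 ± 3.16 to 1118 ± 501).

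At 400 µM, 7580 genes passed in Col-0, 3900 higher and 3680 lower (51.5% higher, 26.9% under total-read scaling, which moved the median from -0.06 to -0.34). HSP23.6 stood at 12590 ± 336 (log2 fold change 12.84, SE 0.61, adjusted p = 1.09e-13), HSP22.0 rose by 12.36 and HSP18.2 by 10.65, while SLAH1 (-7.54), AT3G61400 (-5.37) and the cytokinin hydroxylase CYP735A2 (327 ± 35.5 to 8.69 ± 1.77, -5.09) fell. All 21 heat shock genes rose again (camera adjusted p = 3.28e-35, or 0.00747 with estimated correlation). Detoxification genes had 30 up and 0 down of 36 (camera adjusted p = 5.58e-25, or 0.00412 with estimated correlation). GSTU24 went from 1608 ± 489 to 51950 ± 3630 (5.06, SE 0.24, adjusted p = 1e-13) and UGT74E2 rose by 6.87. Abscisic acid genes had 16 up and 0 down of 20, or 17 up and 1 down over the list alone (camera adjusted p = 4.11e-09, or 0.0519 with estimated correlation). HAI3 rose by 5.99. Sulfur deficiency genes had 11 up and 1 down of 13 (camera adjusted p = 2.07e-06, or 0.187 with estimated correlation). Oxidative stress genes had 10 up and 3 down of 18 (camera adjusted p = 0.00413, or 0.15 with estimated correlation). APX2 rose by 7.54, SE 0.59, adjusted p = 6.11e-10. Aliphatic glucosinolate genes had 0 up and 12 down of 14 (camera adjusted p = 7.79e-11, or 0.15 with estimated correlation). BCAT4 changed by -4.50 and MAM3 by -3.76. Indole glucosinolate genes had 2 up and 9 down of 18, or 3 up and 9 down over the list alone (camera adjusted p = 0.016, or 0.639 with estimated correlation). Camalexin genes had 4 up and 0 down of 8 (camera adjusted p = 0.00413, or 0.576 with estimated correlation). ABCG40 rose by 8.48. Iron deficiency genes had 0 up and 5 down of 14 (camera adjusted p = 0.0198, or 0.582 with estimated correlation). One that fell was the iron transporter IRT1 (6628 ± 3630 to 1562 ± 732, -1.97). Vascular markers had 0 up and 4 down of 9 (camera adjusted p = 0.0411, or 0.576 with estimated correlation). PHO1 changed by -3.34. The clock gene CCA1 rose by 4.87, the lipoxygenase LOX4 by 5.30 and the suberin acyltransferase GPAT5 by 2.48, while the ribonucleotide reductase subunit TSO2 fell by 0.85.

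Between the doses few genes passed: 26 differed in Col_400 against Col_200, 19 higher and 7 lower, with 2417 at an unadjusted p under 0.05. AT1G67300 (a sugar transporter family member) went from 833 ± 196 to 1675 ± 183 (log2 fold change 1.03, SE 0.16, adjusted p = 0.00363) and CAR9 from 230 ± 18 to 468 ± 72.6 (1.01, SE 0.15, adjusted p = 0.00326). With only these groups in the limma fit, 0 genes passed, and the authors' deposited table calls 115. No member of a list passed, while camera placed ribosomal proteins lower (median -0.18, camera adjusted p = 1.32e-08, or 0.838 with estimated correlation), cell cycle genes lower (-0.19, camera adjusted p = 0.000561, or 0.804 with estimated correlation) and abscisic acid genes higher at the higher dose (0.48, camera adjusted p = 4.32e-05, or 0.798 with estimated correlation). Salicylate genes (0.34, camera adjusted p = 0.00583, or 0.804 with estimated correlation) and iron deficiency genes (0.50, camera adjusted p = 0.00773, or 0.804 with estimated correlation) were higher as lists, and sulfur deficiency genes (-0.31, camera adjusted p = 0.0304, or 0.838 with estimated correlation) lower, as were shoot photosynthesis markers (-0.44, camera adjusted p = 0.0304, or 0.838 with estimated correlation). The count rested on single libraries: it was 309 without Col_200 replicate 1, 164 without Col_400 replicate 1, 10 without Col_200 replicate 5, 13 without Col_400 replicate 4 and 7 without Col_400 replicate 5.

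Leaf wounding asked for a response in roots to injury of the shoot. 524 genes passed in Col_w against Col_NT, 382 higher and 142 lower. The groups also differed in incubation, 8 h against 2 h. The 22 jasmonate and wound response genes had 16 up and 0 down, or 20 up and 0 down over the list alone (camera adjusted p = 7.89e-41, or 5.9e-05 with estimated correlation). The repressor JAZ10 rose from 16.7 ± 3.16 to 1118 ± 501 (log2 fold change 5.87, SE 0.44, adjusted p = 2.78e-08), JAZ5 by 3.46 and the storage protein VSP2 by 3.47. Among the largest rises were those of AT1G66860 (0.773 ± 1.34 to 278 ± 86.6, 7.50, SE 0.56, adjusted p = 2.78e-08), AT5G23840 (6.49), the chlorophyllase CLH1 (6.01) and BHLH19 (5.67). AT3G25190, a vacuolar iron transporter family member, fell (598 ± 217 to 131 ± 25.7, -2.14). Indole glucosinolate genes had 8 up and 0 down of 18, or 11 up and 1 down over the list alone (camera adjusted p = 2.69e-08, or 0.113 with estimated correlation). The methyltransferase IGMT5 rose by 1.64, SE 0.27, adjusted p = 0.000555. Genes of glucosinolate breakdown and ER bodies had 4 up and 0 down of 10, or 5 up and 1 down over the list alone (camera adjusted p = 8.72e-06, or 0.0428 with estimated correlation). Among them were the beta-glucosidases BGLU22 (1.74) and BGLU21 (1.14) and the specifier protein NSP1 (1.44). Oxidative stress genes had 4 up and 0 down of 18, or 7 up and 0 down over the list alone (camera adjusted p = 8.72e-06, or 0.03 with estimated correlation). MSRB7 was among them (3.56, SE 0.27, adjusted p = 2.78e-08). Tryptophan and auxin synthesis genes had 3 up and 0 down of 17, or 5 up and 0 down over the list alone (camera adjusted p = 1.96e-05, or 0.0428 with estimated correlation). Iron deficiency genes had 0 up and 3 down of 14, or 0 up and 8 down over the list alone (camera adjusted p = 2.69e-08, or 0.0651 with estimated correlation). Aliphatic glucosinolate genes had 1 up and 0 down of 14, or 2 up and 0 down over the list alone (camera adjusted p = 0.00022, or 0.522 with estimated correlation). Sulfur deficiency genes had 2 up and 0 down of 13, or 4 up and 0 down over the list alone (camera adjusted p = 0.000961, or 0.451 with estimated correlation). Abscisic acid genes had 0 up and 0 down of 20, or 4 up and 0 down over the list alone (camera adjusted p = 0.0041, or 0.451 with estimated correlation, median 0.28). Shoot photosynthesis markers, measured beside these lists as a sign of leaf RNA, had a median of 0.49 with no member passing (camera adjusted p = 0.0214, or 0.677 with estimated correlation). The count of genes fell to 314 without Col_NT replicate 4 and to 348 without Col_w replicate 2.

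Of the genes called after wounding and with 400 µM I3C, 122 were higher and 51 lower in both and 115 went opposite ways, where independent lists would give 70.3, 24.7 and 92.5. Both comparisons share Col_NT, so unchanged groups simulated against it gave an overlap of 0 in 20 simulations but a correlation of fold changes of 0.498 across genes, against 0.146 observed, and a covariance of 0.0686 against 0.0927. Col_NT was too small to split, so part of the excess may come from the shared controls. Without Col_NT replicate 4 the 173 genes of like direction became 87, and without Col_w replicate 4 they became 102.

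The lines were then compared with Col-0 without I3C. Here and below, line differences may hold effects of background beside those of S30. The lines shared their extreme differences: in 107 genes each of the 14 line libraries lay above 4 times the highest of the 12 Col-0 libraries plus 20 counts, and 50 showed the reverse. By the same rule, 1 gene was higher in ICT1-2 alone and 0 in ICT1-8098 alone. In the libraries labelled ICT1-2, 3846 genes passed (2012 higher, 1834 lower), and in ICT1-8098 2579 (1272 higher, 1307 lower). AT5G49440 (chromosome 5, 20048239 to 20049776) went from 0.567 ± 0.492 in Col_NT to 3449 ± 805 in ICT1-2_NT (log2 fold change 11.14, SE 0.46, adjusted p = 4.72e-14) and 3396 ± 543 in ICT1-8098_NT (11.13, SE 0.41, adjusted p = 4.23e-15). AT4G34881 (10.52 and 11.17), AT4G07820 (10.03 and 10.86), AT4G20480 (9.99 and 9.69) and the peroxidase gene PER34 (9.58 and 9.32) were higher in both. PP2A8 was at 0 ± 0 in Col_NT and 1424 ± 260 in ICT1-2_NT (adjusted p = 1.89e-11). The non-coding AT2G05914 (chromosome 2, 2263124 to 2264543) was at 2228 ± 193 in Col_NT and 0 ± 0 in ICT1-2_NT (adjusted p = 3.81e-10). It was at 13.4 ± 21.8 in ICT1-8098_NT (-8.87, SE 0.72, adjusted p = 2.5e-09). AT5G15360, AT4G18150 and AT3G06955 were also lower in ICT1-8098 (-8.55, -8.20 and -8.11). They were at 0 in ICT1-2_NT (adjusted p = 3.96e-09, 1.78e-09 and 5.4e-09). ICT1-8098_NT replicate 5 held more reads of such genes (below), so these ICT1-8098 levels may rest on it.

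**Figure D3:**
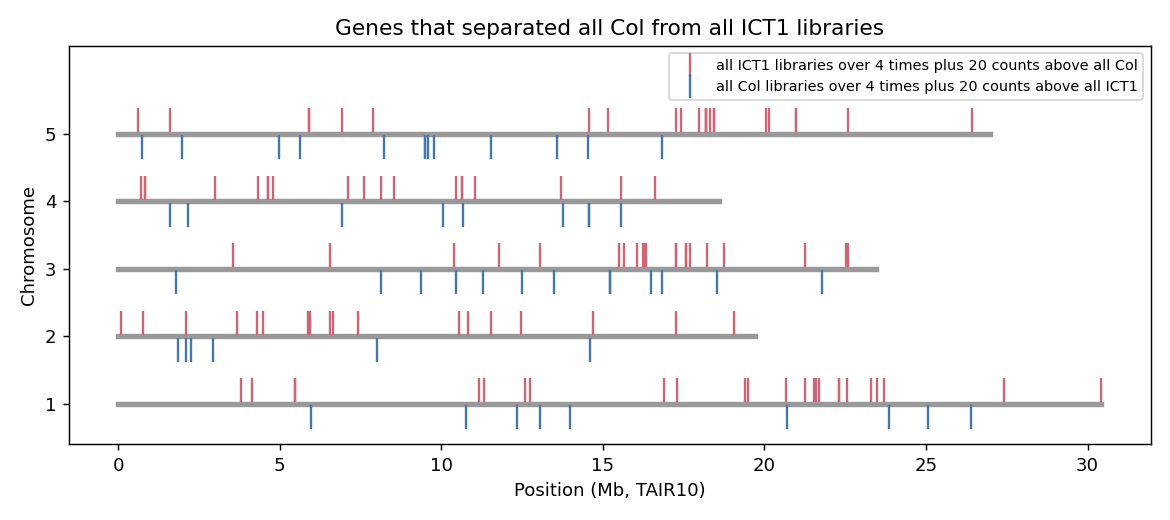
Positions (Mb, TAIR10) on chromosomes 1 to 5 of the 107 genes for which every line library lay above 4 times the highest Col-0 library plus 20 counts, and of the 50 genes with the reverse pattern. Each of the 5 chromosomes holds 18 to 25 of the first kind and 6 to 13 of the second.

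In ICT1-2_NT, jasmonate genes had 14 up and 0 down of 22, or 15 up and 0 down over the list alone (camera adjusted p = 2.12e-06, or 0.369 with estimated correlation). JAZ10 rose from 16.7 ± 3.16 to 158 ± 21.5 (3.17, SE 0.50, adjusted p = 7.14e-05), as did the tyrosine aminotransferase TAT3 (4.56) and JAZ5 (2.84). Iron deficiency genes had 0 up and 7 down of 14, or 0 up and 9 down over the list alone (camera adjusted p = 0.000186, or 0.745 with estimated correlation), with the regulators ORG2 (-3.10, SE 0.62, adjusted p = 0.00112) and ORG3 (-2.54). Ribosomal proteins had 11 up and 18 down of 297, or 7 up and 6 down over the list alone, median -0.19 (camera adjusted p = 0.0113, or 0.953 with estimated correlation; 12 up and 11 down under total-read scaling). Aliphatic glucosinolate genes had 0 up and 2 down of 14 (camera adjusted p = 0.0113, or 0.953 with estimated correlation), namely the sulfotransferases SOT17 (-1.38) and SOT18 (-1.24). Outside lists that passed, the tryptophan synthase subunit TSB2 fell from 867 ± 17.45 to 196 ± 2.26 (-2.14, SE 0.14, adjusted p = 1.05e-10), the superoxide dismutases CSD2 (-1.75) and CSD1 (-1.51) and the immune regulator ALD1 (-2.35) fell, and the nitrilase NIT1 (1.57) and CBP60G, a regulator of salicylate synthesis (2.01), rose. With 2 libraries in ICT1-2_NT the count rested on single libraries: it was 2492 without Col_NT replicate 4, 2308 without ICT1-2_NT replicate 1 and 1973 without replicate 2. The share of called genes that were higher was 52.3%, or 64.2% under total-read scaling.

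In ICT1-8098_NT, shoot photosynthesis markers had 0 up and 8 down of 14, or 0 up and 11 down over the list alone (camera adjusted p = 2.84e-06, or 0.662 with estimated correlation), with RBCS3B (51.2 ± 19.6 to 1.83 ± 1.88, -4.40, SE 0.79, adjusted p = 0.00036) and the light-harvesting genes CAB3 (-4.34) and LHCB2.1 (-3.64). In ICT1-2_NT no member passed (median -0.19). Moving with them, iron deficiency genes had 0 up and 9 down of 14, or 0 up and 12 down over the list alone (camera adjusted p = 2.84e-06, or 0.532 with estimated correlation). ORG3 changed by -2.12. Salicylate genes had 0 up and 5 down of 15, or 0 up and 6 down over the list alone (camera adjusted p = 0.00254, or 0.662 with estimated correlation). ALD1 changed by -2.42. Ethylene genes had 0 up and 5 down of 15, or 1 up and 6 down over the list alone (camera adjusted p = 0.00426, or 0.532 with estimated correlation). ERF2 changed by -2.33. Abscisic acid genes had 0 up and 4 down of 20, or 0 up and 6 down over the list alone (camera adjusted p = 0.0208, or 0.662 with estimated correlation). The dehydrin RAB18 went from 248 ± 74.1 to 5.69 ± 3.65 (-5.36, SE 0.95, adjusted p = 0.000347). For aliphatic glucosinolate genes, the counts were 0 up and 3 down of 14 (camera adjusted p = 0.00723, or 0.662 with estimated correlation), led by CYP79F1 (-4.25) and the regulator MYB29 (-4.15). Detoxification genes had 2 up and 8 down of 36, or 2 up and 10 down over the list alone (camera adjusted p = 0.0411, or 0.662 with estimated correlation). GSTU24 changed by -2.31 and GSTU9 by 1.67. Sulfur deficiency genes had 4 up and 0 down of 13, or 6 up and 0 down over the list alone (camera adjusted p = 0.00254, or 0.662 with estimated correlation). Heat shock genes had 2 up and 0 down of 21, or 4 up and 0 down over the list alone (camera adjusted p = 0.00254, or 0.662 with estimated correlation), including HSP18.2 (3.16). Ribosomal proteins had 9 up and 13 down of 297, or 6 up and 3 down over the list alone, median -0.22 (camera adjusted p = 0.000595, or 0.902 with estimated correlation; 10 up and 10 down under total-read scaling). Without Col_NT replicate 4 the count of genes was 1702.

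The lines differed from Col-0 in much the same direction: 969 genes were higher and 800 lower in both and 28 went opposite ways, where independent lists would give 121, 113 and 234. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.84, against 0.448 for unchanged groups simulated against the same Col_NT libraries, and the covariance was 0.937 against 0.0693. The simulated overlap was 0 in 20 simulations, where hardly any gene passes, so it cannot gauge the overlap among changed genes. Again, part of the excess may come from the shared controls. Genes called the same way in both lines against Col_NT and with both I3C doses in Col-0 numbered 108 higher and 124 lower, and 168 went opposite ways in the lines and with I3C, where independent lists would give 132, 84.0 and 211 (0 in 20 simulations of unchanged groups; all 4 comparisons share Col_NT). Those with the smallest p-values included PER34, of the 107 genes above, and AT1G17145 (1.85 in ICT1-2_NT). Others were HTT2 (2.39 and, in ICT1-8098_NT, 2.94), the splicing factor SR33 (1.203) and, lower, AT1G60690 (-1.94). Between comparisons that share no library, changes in ICT1-8098_NT and with 200 µM I3C in ICT1-2 were higher in both for 106 genes, lower in both for 95 and opposite for 422, where independent lists would give 150, 88.4 and 240. In the exchange, genes of ICT1-2_NT and the I3C response of ICT1-8098 gave 382, 273 and 388, where independent lists would give 285, 146 and 420. The 201 genes of like direction in the former became 114 without ICT1-2_NT replicate 1, and the 655 in the latter became 398 and 298 without ICT1-2_NT replicates 1 and 2.

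I3C was then compared with DMSO within each line. The lines responded, and all 21 heat shock genes rose in each comparison. 3935 genes passed in ICT1-2 at 200 µM (2503 higher, 1432 lower), 4691 in ICT1-8098 at 200 µM (3003 and 1688) and 6644 in ICT1-2 at 400 µM (3737 and 2907). HSP17.4 rose from 3.6 ± 0.976 to 3288 ± 379 in ICT1-2 (log2 fold change 9.49, SE 0.35, adjusted p = 1.35e-14) and from 5.45 ± 3.21 to 4630 ± 1680 in ICT1-8098 (9.52, SE 0.32, adjusted p = 1.39e-15) at 200 µM, and HSP22.0 from 2.63 ± 2.35 to 9067 ± 2080 in ICT1-2 at 400 µM (11.43, SE 0.55, adjusted p = 1.99e-13). AT1G71000 rose by 10.22, 10.79 and 12.17 in these comparisons. AT1G33840 fell in both lines at 200 µM (-5.22 and -4.61), with the homocysteine methyltransferase HMT3 in ICT1-2 (-4.14), the cytochrome P450 CYP702A5 in ICT1-8098 (-4.59), and PER59 (-4.59) and the aspartate kinase AK3 (-4.12) in ICT1-2 at 400 µM. The shares of called genes that were higher were 63.6%, 64.0% and 56.2%, or 33.8%, 41.0% and 20.13% under total-read scaling, which moved the medians from -0.03 to -0.27, from -0.04 to -0.22 and from -0.07 to -0.51. For ICT1-2 the count at 200 µM was 2457 without ICT1-2_NT replicate 1 and 2375 without replicate 2, and at 400 µM 4413 without replicate 1.

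At 200 µM in ICT1-2, all 21 heat shock genes rose (camera adjusted p = 9.45e-48, or 0.00166 with estimated correlation). Detoxification genes had 31 up and 0 down of 36, or 32 up and 0 down over the list alone (camera adjusted p = 1.03e-31, or 0.00112 with estimated correlation). GSTU5 went from 51.7 ± 21.6 to 3417 ± 1310 (6.02, SE 0.35, adjusted p = 1.02e-11). For sulfur deficiency genes, the counts were 11 up and 0 down of 13, or 11 up and 1 down over the list alone (camera adjusted p = 7.68e-13, or 0.0434 with estimated correlation). LSU1 rose by 5.17. For aliphatic glucosinolate genes, the counts were 0 up and 12 down of 14, or 0 up and 13 down over the list alone (camera adjusted p = 3.53e-09, or 0.164 with estimated correlation). CYP83A1 changed by -2.21. Camalexin genes had 7 up and 0 down of 8, or 8 up and 0 down over the list alone (camera adjusted p = 3.35e-08, or 0.0999 with estimated correlation), with CYP71A12 (3.43, SE 0.56, adjusted p = 9.12e-05). For abscisic acid genes, the counts were 10 up and 0 down of 20, or 14 up and 0 down over the list alone (camera adjusted p = 3.12e-06, or 0.0999 with estimated correlation). Oxidative stress genes had 10 up and 2 down of 18 (camera adjusted p = 0.000327, or 0.0639 with estimated correlation). Clock genes had 7 up and 0 down of 12 (camera adjusted p = 0.0014, or 0.164 with estimated correlation). PRR9 rose by 2.41. Unfolded protein response genes had 4 up and 0 down of 11, with a median of 0.17 that became -0.07 under total-read scaling (camera adjusted p = 0.00916, or 0.242 with estimated correlation). Moving with these, shoot photosynthesis markers had 0 up and 11 down of 14 (camera adjusted p = 1.45e-06, or 0.226 with estimated correlation). LHCB2.1 went from 21.1 ± 6.51 to 0.617 ± 0.539 (-3.81). Root hair markers had 0 up and 0 down of 7 (camera adjusted p = 0.0481, or 0.654 with estimated correlation, median -0.89).

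In ICT1-8098 at 200 µM, all 21 heat shock genes rose (camera adjusted p = 4.5e-42, or 0.00317 with estimated correlation). Detoxification genes had 32 up and 0 down of 36, or 33 up and 0 down over the list alone (camera adjusted p = 2.35e-33, or 0.000838 with estimated correlation). GSTU4 went from 34.7 ± 22.9 to 1607 ± 643 (5.60, SE 0.35, adjusted p = 2.24e-11). For abscisic acid genes, the counts were 16 up and 0 down of 20, or 17 up and 0 down over the list alone (camera adjusted p = 6.57e-12, or 0.0175 with estimated correlation). NCED3 rose by 4.75. For aliphatic glucosinolate genes, the counts were 0 up and 12 down of 14 (camera adjusted p = 1.42e-09, or 0.153 with estimated correlation). MAM1 changed by -2.62. Indole glucosinolate genes had 1 up and 9 down of 18, or 3 up and 10 down over the list alone (camera adjusted p = 0.0103, or 0.481 with estimated correlation). CYP79B3 changed by -2.15 and MYB51 by 1.96. For sulfur deficiency genes, the counts were 10 up and 0 down of 13, or 11 up and 1 down over the list alone (camera adjusted p = 1.05e-07, or 0.141 with estimated correlation). Camalexin genes had 6 up and 0 down of 8 (camera adjusted p = 5.82e-06, or 0.153 with estimated correlation). Clock genes had 6 up and 0 down of 12, or 7 up and 0 down over the list alone (camera adjusted p = 0.000997, or 0.153 with estimated correlation). For oxidative stress genes, the counts were 10 up and 4 down of 18, or 11 up and 4 down over the list alone (camera adjusted p = 0.00128, or 0.11 with estimated correlation). Autophagy genes had 7 up and 0 down of 22 (camera adjusted p = 0.00485, or 0.479 with estimated correlation). ATG8H rose by 1.94, SE 0.22, adjusted p = 3.05e-07. Salicylate genes had 6 up and 0 down of 15 (camera adjusted p = 0.0173, or 0.481 with estimated correlation). WRKY70 rose by 1.90. Cell cycle genes had 1 up and 2 down of 23, or 0 up and 0 down over the list alone (camera adjusted p = 0.026, or 0.569 with estimated correlation, median -0.30). Without ICT1-8098_200 replicate 2, indole glucosinolate (adjusted p = 0.101), salicylate (0.0888) and cell cycle genes (0.0613) were not called, and ethylene genes were (0.0484). The myrosinase-like PYK10 of ER bodies fell from 79440 ± 7170 to 28530 ± 7410 (-1.51). Shoot photosynthesis markers did not pass as a list (median -0.72, camera adjusted p = 0.0663).

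In ICT1-2 at 400 µM, all 21 heat shock genes rose (camera adjusted p = 4.9e-39, or 0.00458 with estimated correlation). Detoxification genes had 32 up and 1 down of 36, or 33 up and 1 down over the list alone (camera adjusted p = 5.16e-26, or 0.00333 with estimated correlation), and all 14 aliphatic glucosinolate genes fell (camera adjusted p = 4.38e-09, or 0.169 with estimated correlation). The regulator MYB28 went from 833 ± 41.4 to 74.3 ± 24.7 (-3.52, SE 0.46, adjusted p = 2.11e-06). For sulfur deficiency genes, the counts were 11 up and 0 down of 13 (camera adjusted p = 4.94e-12, or 0.0548 with estimated correlation). LSU2 went from 51.2 ± 5.81 to 3340 ± 712 (5.98). For abscisic acid genes, the counts were 13 up and 0 down of 20 (camera adjusted p = 6.49e-07, or 0.0683 with estimated correlation). Clock genes had 7 up and 0 down of 12, or 9 up and 0 down over the list alone (camera adjusted p = 2.09e-05, or 0.0683 with estimated correlation). CCA1 rose by 4.18. Camalexin genes had 6 up and 0 down of 8 (camera adjusted p = 0.000164, or 0.289 with estimated correlation). For oxidative stress genes, the counts were 10 up and 1 down of 18 (camera adjusted p = 0.000309, or 0.0625 with estimated correlation). Jasmonate genes had 1 up and 6 down of 22 (camera adjusted p = 0.0205, or 0.498 with estimated correlation; 0 up and 13 down under total-read scaling). JAZ7 changed by -3.05, SE 0.55, adjusted p = 0.000161, and the allene oxide synthase AOS by -1.61. Cell cycle genes had 0 up and 8 down of 23, or 0 up and 9 down over the list alone (camera adjusted p = 0.00695, or 0.515 with estimated correlation). The replication helicase subunit MCM5 changed by -0.97. Autophagy genes had 9 up and 0 down of 22, with a median of 0.23 that became -0.21 under total-read scaling (camera adjusted p = 0.00809, or 0.498 with estimated correlation). Root hair markers had 0 up and 3 down of 7, or 0 up and 4 down over the list alone (camera adjusted p = 0.0402, or 0.58 with estimated correlation). Shoot photosynthesis markers moved with these lists, with 0 up and 9 down of 14, or 1 up and 9 down over the list alone (camera adjusted p = 0.00867, or 0.58 with estimated correlation).

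The 200 µM responses were compared over genes chosen in another line. Over the 4691 genes called in ICT1-8098, 95.1% moved the same way in ICT1-2, with a median log2 change in the called direction of 0.84, and 96.0% did so in Col-0, with a median of 1.0. Over the 3935 genes called in ICT1-2, 96.2% moved the same way in ICT1-8098 (median 0.93) and 93.6% in Col-0 (median 0.97). Differences between these medians were not tested. GSTU5 rose by 7.12 in Col-0, 6.02 in ICT1-2 and 5.54 in ICT1-8098.

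With 200 µM I3C, 4576 genes differed between ICT1-2 and Col-0 (2424 higher, 2152 lower in ICT1-2) and 5133 between ICT1-8098 and Col-0 (2642 and 2491), and with 400 µM 5510 between ICT1-2 and Col-0 (2993 and 2517). AT2G11225 (10.61, 10.46 and 10.60) and the disease resistance family gene AT5G51630 (10.34, 10.30 and 10.34) were higher in all 3 comparisons, and AT2G05914 was lower in ICT1-2 (-10.86 and -10.40). The glutathione transferase GSTU24 was lower in both lines at 200 µM (47210 ± 6820 in Col-0, 7877 ± 690 in ICT1-2 and 6424 ± 2040 in ICT1-8098, -2.58, SE 0.24, adjusted p = 2.39e-08 and -2.93, SE 0.24, adjusted p = 2.58e-09) and in ICT1-2 at 400 µM (-1.97). TSB2 was lower (-1.24, -1.498 and -1.65), as was ALD1 (-2.67, -2.58 and -2.32), while CBP60G was higher (3.09, 2.33 and 2.04). The share of called genes that were higher was 53.0% for ICT1-2 and 51.5% for ICT1-8098 at 200 µM, or 74.1% and 76.9% under total-read scaling, which moved the medians from 0.01 to 0.18 and from 0.01 to 0.21. At 400 µM it was 54.3%, or 45.0% under that scaling. Without Col_200 replicate 4 the counts at 200 µM were 2904 and 2938, and for ICT1-8098 the count was 3320 without ICT1-8098_200 replicate 2.

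At 200 µM against Col-0, ribosomal proteins had 6 up and 82 down of 297, or 7 up and 108 down over the list alone in ICT1-2 (camera adjusted p = 1.89e-11, or 0.769 with estimated correlation) and 7 up and 167 down of 297, or 8 up and 197 down over the list alone in ICT1-8098 (camera adjusted p = 1.05e-18, or 0.859 with estimated correlation). With total-read scaling 39 and 98 members passed lower, and in ICT1-8098 heat shock genes had 1 up and 1 down, detoxification genes 3 up and 6 down and cell cycle genes 1 up and 1 down. Shoot photosynthesis markers were lower beside them, with 0 up and 13 down of 14 in ICT1-2 (camera adjusted p = 1.89e-11, or 0.544 with estimated correlation) and 0 up and 13 down of 14 in ICT1-8098 (camera adjusted p = 1.2e-11, or 0.537 with estimated correlation), and CAB3 at 382 ± 308 in Col-0, 10.3 ± 3.2 in ICT1-2 (-4.79) and 7.04 ± 4.65 in ICT1-8098 (-5.42). Heat shock genes had 0 up and 6 down of 21, or 0 up and 9 down over the list alone in ICT1-2 (camera adjusted p = 0.00211, or 0.769 with estimated correlation) and 0 up and 4 down of 21 in ICT1-8098 (camera adjusted p = 0.0243, or 0.859 with estimated correlation). In ICT1-2, HSP22.0 changed by -2.35, SE 0.49, adjusted p = 0.00141. ICT1-8098_200 replicate 2 stood apart: its median response to I3C was 0.40, against 0.63 and 0.68 in replicates 3 and 4, with HSP23.6 at 1616 against 7900 and 8190. In a test added after seeing the data, without it, camera no longer called heat shock (adjusted p = 0.810), detoxification (0.271) or cell cycle genes (0.0573) for ICT1-8098 and called clock genes (0.0145). Ribosomal proteins had 5 up and 100 down. In ICT1-2, jasmonate genes had 8 up and 0 down of 22 (camera adjusted p = 0.00135, or 0.769 with estimated correlation). JAZ5 changed by 2.88. The abscisic acid genes numbered 0 up and 7 down of 20 (camera adjusted p = 0.00695, or 0.769 with estimated correlation). RD22 changed by -1.48. CYP79B3 (1.499, SE 0.26, adjusted p = 0.00017) and MAM1 (1.91) were higher than in Col-0. In ICT1-8098, detoxification genes had 2 up and 11 down of 36, or 2 up and 12 down over the list alone (camera adjusted p = 0.0375, or 0.859 with estimated correlation). Cell cycle genes had 0 up and 5 down of 23, or 0 up and 6 down over the list alone, with a median of -0.19 that became 0.02 under total-read scaling (camera adjusted p = 0.0477, or 0.859 with estimated correlation). The transcription factor ERF1 was lower (-2.39, SE 0.47, adjusted p = 0.000721) and the clock gene ELF4 higher (1.45).

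At 400 µM, sulfur deficiency genes were higher in ICT1-2 than in Col-0, with 11 up and 0 down of 13, or 12 up and 0 down over the list alone (camera adjusted p = 2.85e-06, or 0.457 with estimated correlation). Among them were LSU1 at 460 ± 113 in Col-0 and 1842 ± 613 in ICT1-2 (1.96, SE 0.42, adjusted p = 0.00139), SHM7 (1.87) and LSU2 (1.71). Clock genes had 7 up and 0 down of 12 (camera adjusted p = 0.000154, or 0.457 with estimated correlation). PRR7 changed by 2.08 and PRR5 by 1.85. Genes of glucosinolate breakdown and ER bodies had 6 up and 0 down of 10, or 7 up and 0 down over the list alone (camera adjusted p = 0.0072, or 0.509 with estimated correlation). BGLU21 changed by 0.95. Heat shock genes had 6 up and 0 down of 21 (camera adjusted p = 0.0135, or 0.743 with estimated correlation). The disaggregase HSP101 changed by 1.27, SE 0.29, adjusted p = 0.00268. The abscisic acid genes numbered 1 up and 8 down of 20, or 1 up and 11 down over the list alone (camera adjusted p = 0.00636, or 0.649 with estimated correlation). RD29B changed by -5.05, SE 0.77, adjusted p = 3.5e-05, and RAB18 by -4.10. For cell cycle genes, the counts were 1 up and 6 down of 23, or 1 up and 7 down over the list alone (camera adjusted p = 0.0395, or 0.743 with estimated correlation). MCM5 changed by -0.62. Ribosomal proteins had 9 up and 33 down of 297, or 6 up and 16 down over the list alone (camera adjusted p = 0.000104, or 0.743 with estimated correlation). Shoot photosynthesis markers were again lower, with 0 up and 10 down of 14 (camera adjusted p = 7.19e-05, or 0.649 with estimated correlation).

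Interaction terms tested whether the I3C response differed between a line and Col-0. 144 genes passed for ICT1-2 at 200 µM (71 positive and 73 negative terms), 56 for ICT1-8098 at 200 µM (31 and 25) and 471 for ICT1-2 at 400 µM (286 and 185). PER34, at 2.82 ± 2.54 in Col_NT and 2328 ± 544 in ICT1-2_NT, gave interactions of -5.15, SE 0.60, adjusted p = 9.48e-05 for ICT1-2 at 200 µM and of -6.18, SE 0.60, adjusted p = 3.54e-06 at 400 µM. AT4G02550 gave 2.70, SE 0.27, adjusted p = 6.83e-06 for ICT1-8098 and 3.90, SE 0.28, adjusted p = 3.25e-08 for ICT1-2 at 400 µM, the meiotic gene ASY2 -3.81 for ICT1-8098 and AT5G23510 3.03 for ICT1-2 at 400 µM. The clock gene PRR7 had a positive term for ICT1-2 at 400 µM (2.49, SE 0.34, adjusted p = 0.000496), as did ELF4 (1.59) and the sulfate reduction enzyme APR1 (2.41, SE 0.31, adjusted p = 0.000239), and the fall of MAM3 was smaller there (2.37).

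Of the lists, shoot photosynthesis markers differed for ICT1-2 at 200 µM, with 0 up and 4 down of 14, or 0 up and 11 down over the list alone (camera adjusted p = 1.96e-15, or 0.217 with estimated correlation). For heat shock genes, the counts were 0 up and 1 down of 21, or 0 up and 4 down over the list alone (camera adjusted p = 3.06e-05, or 0.405 with estimated correlation). For indole glucosinolate genes, the counts were 1 up and 0 down of 18, or 7 up and 1 down over the list alone (camera adjusted p = 9.59e-07, or 0.298 with estimated correlation). The aliphatic glucosinolate genes numbered 1 up and 1 down of 14, or 9 up and 2 down over the list alone (camera adjusted p = 3.5e-05, or 0.405 with estimated correlation). For ICT1-8098, ribosomal proteins had 0 up and 0 down of 297 (camera adjusted p = 8e-16, or 0.489 with estimated correlation), median -0.31. For heat shock genes, the counts were 0 up and 1 down of 21, or 0 up and 11 down over the list alone (camera adjusted p = 9.41e-13, or 0.305 with estimated correlation), median -1.11, or -0.68 without ICT1-8098_200 replicate 2 (3.70e-07). For iron deficiency genes, the counts were 1 up and 0 down of 14, or 6 up and 0 down over the list alone (camera adjusted p = 1.07e-06, or 0.305 with estimated correlation). Shoot photosynthesis markers had 0 up and 0 down of 14, or 0 up and 5 down over the list alone (camera adjusted p = 1.61e-06, or 0.389 with estimated correlation). For ICT1-2 at 400 µM, sulfur deficiency genes had 5 up and 0 down of 13, or 9 up and 0 down over the list alone (camera adjusted p = 3.97e-09, or 0.156 with estimated correlation). Clock genes had 4 up and 0 down of 12, or 6 up and 0 down over the list alone (camera adjusted p = 4.07e-05, or 0.156 with estimated correlation). Jasmonate genes had 0 up and 1 down of 22, or 0 up and 6 down over the list alone (camera adjusted p = 3.6e-06, or 0.156 with estimated correlation). Shoot photosynthesis markers had 0 up and 0 down of 14, or 0 up and 8 down over the list alone (camera adjusted p = 4.07e-05, or 0.49 with estimated correlation). Camera called 13, 13 and 11 lists here, and 0 with an estimated correlation.

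The interaction counts were small beside those of the responses and rested on single libraries. For ICT1-2 at 200 µM the count was 232, 50, 67 without Col_NT replicates 3, 4, 5, 393, 67 without Col_200 replicates 1, 4, 30, 29 without ICT1-2_NT replicates 1, 2, 54, 77 without ICT1-2_200 replicates 2, 4. For ICT1-8098 it was 95, 29, 32 without Col_NT replicates 3, 4, 5, 369, 31 without Col_200 replicates 1, 4, 33, 35, 35 without ICT1-8098_NT replicates 1, 4, 5, 32 without ICT1-8098_200 replicate 3. For ICT1-2 at 400 µM it was 270 without Col_NT replicate 4, 708 without Col_400 replicate 1, 143, 248 without ICT1-2_NT replicates 1, 2, 230 without ICT1-2_400 replicate 5. The share of positive terms was 55.4% for ICT1-8098 at 200 µM and 60.7% for ICT1-2 at 400 µM, or 71.2% and 35.1% under total-read scaling, which moved the medians from 0.02 to 0.15 and from 0.01 to -0.14.

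**Figure D4:**
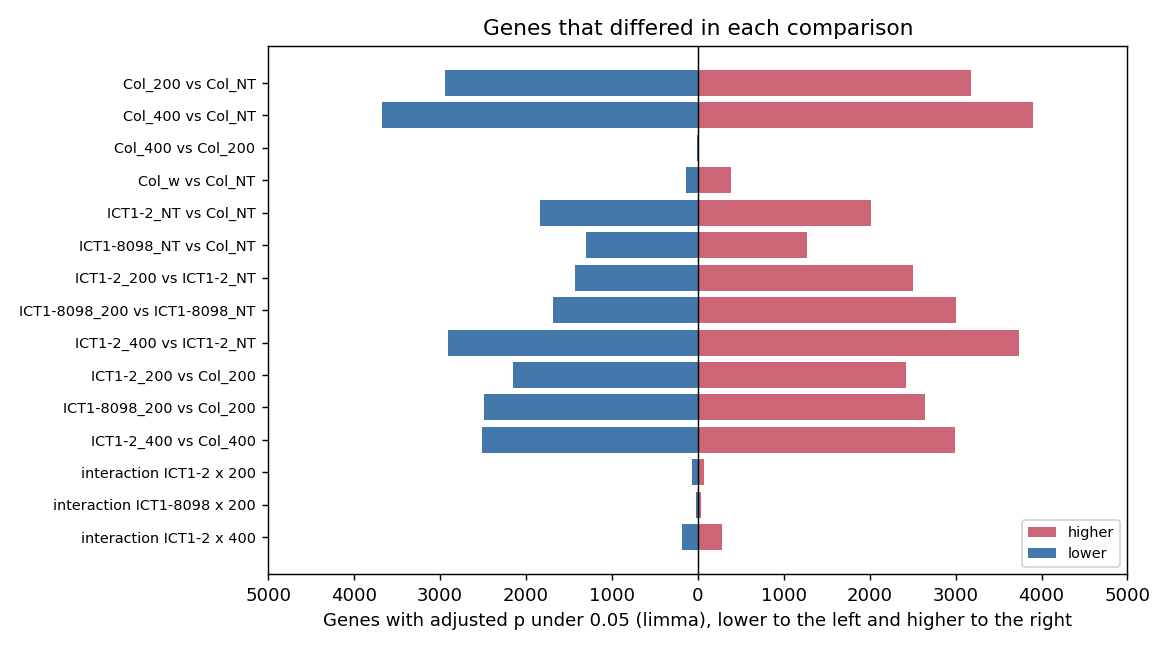
Genes passing an adjusted p of 0.05 in each of the 15 comparisons (bars, number of genes), higher or lower in the group named first and, for interactions, with a positive or negative term. The counts run from 26 between the I3C doses to 7580 for 400 µM I3C in Col-0.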

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

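Of these tests, the splits of the libraries were chosen before the result was seen. Those on the S30 genes and on reads in a single library were chosen only after it.

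The I3C response differed between a line and Col-0, by interaction terms, for 144 genes for ICT1-2 at 200 µM, 56 for ICT1-8098 at 200 µM and 471 for ICT1-2 at 400 µM. For ICT1-8098, 12 of 100 splits of the libraries, the real one included, gave as many genes or more, and the highest other split gave 2470. The splits mixed the line labels separately with and without I3C, so the difference between the lines could itself enter the term. These splits therefore cannot judge this count, and chance was not excluded for it. Single libraries moved the counts widely. Without Col_NT replicate 4 they were 50, 29 and 270. Without replicate 1 of Col_200 or Col_400 they were 393, 369 and 708. The libraries that moved a count by more than 1.5 times are those given with the interaction counts above.

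No S30 gene was higher in the libraries labelled ICT1-2 than in Col-0, although the label names S30 overexpression. Reads shared between the copies could hide a small rise. The summed counts of the 3 genes had an upper 95% bound of 0.233 (log2) in ICT1-2_NT against Col_NT. In ICT1-8098_NT, where RPS30A rose, the sum changed by only 0.29 (-0.018 to 0.60), so this stays open without I3C. With 200 µM I3C the sum differed from Col-0 by -0.36 in ICT1-2 (-0.67 to -0.052) and by 0.28 in ICT1-8098 (-0.027 to 0.59). These values argue against a hidden rise in ICT1-2 at that dose. With 400 µM the sum in ICT1-2 differed by -0.30 (-0.61 to 0.012). An exchange with Col-0 libraries was argued against by 182 genes chosen without ICT1-2, at 98.35% or more of which each ICT1-2 library lay nearer to ICT1-8098 than to Col-0. Transgenes whose transcripts the annotation does not count, or a line with another content than its label, were not tested and stay open.

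ICT1-8098_NT replicate 5 held more reads of genes far higher in Col-0 than other line libraries did. Over 42 such genes its median level was 3.43% of Col_NT and 1 gene had no reads, where each other line library had a median of 0 and 24 to 31 genes without reads. Lower depth was argued against, since the lowest other library of the group had 1.1 times its reads. Reads of a Col-0 library mixed in may be the source: 78.6% of the 42 genes lay within 0.5 to 2 times the median share, just under the 80% set as the bound, so this stays open. Genes called in ICT1-8098_NT against Col_NT were 1844 without it, and 1952 and 1823 without replicates 1 and 4. The fall is thus not particular to it.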

How the results depend on the processing

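Alternatives named above as added were chosen only after the data were seen. The planned negative binomial Wald test was not run, and voom was the only test on recovered reads. Over all settings the named genes gave 20702 values, of which 18842 kept their direction and side of the threshold, 1805 no longer passed, 54 newly passed and 1 reversed: TSB2 in ICT1-2_400 against ICT1-2_NT, at -0.028 under total-read scaling (adjusted p = 0.888, and 0.0322 as reported), a scaling that lowers the median of this comparison from -0.07 to -0.51. A stricter threshold leaves fewer calls by construction. For the other changes the cause was not tested.

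With only the compared groups in the fit, which has fewer libraries to estimate the spread, 3638 genes passed for Col_200 against Col_NT, 0 for Col_400 against Col_200 (limma, 2417 at an unadjusted p under 0.05 in the fit of all libraries, 115 in the authors' deposited table), 277 for Col_w, 2380 and 1476 for ICT1-2_200 and ICT1-8098_200 against Col_200, 32 and 6 for the interactions at 200 µM of ICT1-2 and ICT1-8098, and 59 in the overlap of wounding with 400 µM I3C. With an absolute log2 fold change over 1, the counts were 3304 for Col_200, 3895 for Col_400, 15 between the doses, 2021 and 1466 for ICT1-2_NT and ICT1-8098_NT against Col_NT, 2208, 2544 and 3471 for ICT1-2_200, ICT1-8098_200 and ICT1-2_400 against their own lines, 2128, 2189 and 2655 for ICT1-2_200, ICT1-8098_200 and ICT1-2_400 against Col-0, and 1058, 104, 292 and 97 for the overlaps. The authors' deposited table calls 809 genes for wounding. Total-read scaling gave 10676 genes for ICT1-2_400 against ICT1-2_NT, and voom gave 46 and 15 for the interactions at 200 µM. The median 200 µM responses over genes called in ICT1-8098, in ICT1-2 and Col-0, were 0.71 and 0.85 with total-read scaling. Over genes past the fold threshold they were 1.43 and 1.70. That of ICT1-2 was 0.81 with the filter at 5 CPM, a pseudocount of 5, voom or replicate numbers 4 and 5 as a block. Over genes called in ICT1-2, the medians in ICT1-8098 and Col-0 were 0.68 and 0.82 with total-read scaling and 1.64 and 1.69 past the fold threshold. With an estimated correlation, the lists called numbered 2, 2, 0 and 4 for Col_200, Col_400, Col_400 against Col_200 and wounding, 0 and 0 for the lines without I3C, 3, 3 and 2 for I3C in ICT1-2 at 200 µM, ICT1-8098 and ICT1-2 at 400 µM, and 0 for each of the lines against Col-0 with I3C and each interaction. Without ICT1-8098_200 replicate 2, 3 lists were called for ICT1-8098_200 against Col_200.

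Replicate numbers did not pair the libraries: over 62 same-numbered pairs of libraries in different groups the median correlation of deviations was 0.000846 (-0.241 to 0.299), and 6 of 26 libraries correlated best with their own number, a hint from the data and not from the design. With the replicate block, the interaction of ICT1-2 at 200 µM had 305 genes, the overlap of wounding with 400 µM I3C 285, the lists called for ICT1-8098_200 against Col_200 were 2, and the median responses were 0.89 in ICT1-2 and 1.09 in Col-0 over genes called in ICT1-8098, and 1.05 in Col-0 over genes called in ICT1-2. The other total counts of genes stayed within 1.5 times under the block. Some counts by direction did not: genes lower than in ICT1-2_NT went from 2907 to 1514 in ICT1-2_400 and from 1432 to 857 in ICT1-2_200.

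Leaving out 1 library at a time, with a lone ICT1-2_NT library assumed to vary like the other groups, gave 4757 to 7288 genes for Col_200, 6161 to 7774 for Col_400, 7 to 309 between the doses and 314 to 558 for wounding. For the lines without I3C it gave 1973 to 3861 for ICT1-2 and 1702 to 2701 for ICT1-8098. I3C within lines gave 2375 to 3455, 3514 to 4472 and 4413 to 5920 for ICT1-2_200, ICT1-8098_200 and ICT1-2_400, and the same groups against Col-0 gave 2904 to 5556, 2938 to 6692 and 3895 to 5560. The interactions ran over 29 to 393, 29 to 369 and 143 to 708, and the overlaps over 1196 to 1908 between the lines, 114 to 184 and 298 to 613 between a line and the I3C response of the other, and 87 to 214 for wounding with 400 µM I3C. The median responses ran over 0.824 to 1.014 and 0.9547 to 1.215 over genes called in ICT1-8098, in ICT1-2 and Col-0, and over 0.8605 to 1.253 and 0.9201 to 1.306 over genes called in ICT1-2, in ICT1-8098 and Col-0. At this depth, 4.41% of 1.5-fold interactions were recovered in simulated data, so small differences of response between lines were mostly not detectable.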

Other observations

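Some members of lists moved apart under I3C. In the ethylene list, ACS7, which makes the ethylene precursor, rose in ICT1-2 (3.11, SE 0.52, adjusted p = 9.7e-05 at 200 µM and 5.02 at 400 µM) and in ICT1-8098 (4.59), while the transcription factor ORA59 fell in ICT1-8098 (-3.09, SE 0.79, adjusted p = 0.00518) and in ICT1-2 at 400 µM (49.3 ± 3.06 to 3.18 ± 2.61, -3.79). In the indole glucosinolate list, the regulator MYB51 rose at 200 µM in ICT1-2 (1.92, SE 0.38, adjusted p = 0.000614) and ICT1-8098 (1.96), as did the hydroxylase CYP81F2 in ICT1-2 (2.64), while MYB34 fell in ICT1-8098 (-1.34) and in ICT1-2 at 400 µM (-1.84). The nitrile specifier protein NSP5 rose with I3C in Col_200 (2.38), ICT1-2_200 (1.94), ICT1-8098_200 (2.44) and ICT1-2_400 (3.13, SE 0.28, adjusted p = 6.99e-09), and the transporter PEN3 rose in ICT1-2 at both doses (2.06 and 2.31), while the ER body genes PYK10, NAI2 (-1.68) and BGLU22 (-1.15) fell in ICT1-8098 (PYK10 at -1.51).

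Of the suberin markers, which did not pass as a list (camera adjusted p = 0.0855 in ICT1-2 and 0.391 in ICT1-8098), some rose at 200 µM: the feruloyl transferase ASFT in ICT1-2 (449 ± 82.3 to 2348 ± 404, 2.38, SE 0.40, adjusted p = 0.000128) and in ICT1-8098 (1.65), and GPAT5 in ICT1-2 (2.50). BZIP60, a transcription factor of the unfolded protein response, rose in Col_200 (1.46), ICT1-2_200 (1.88), ICT1-8098_200 (1.51) and ICT1-2_400 (1.83, SE 0.20, adjusted p = 1.41e-07). The tryptophan synthase subunit TSB1 rose in ICT1-2 at 200 µM (1.32) and 400 µM (1.70), and PID, a kinase that directs auxin efflux, in Col_200 (1.83), ICT1-8098_200 (1.74) and ICT1-2_400 (1.92). For 116 genes every library with I3C lay above 4 times the highest without it plus 20 counts, and 1 showed the reverse.

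For the differences between the lines and Col-0, the tests on neighbouring genes, on S30 levels and on linkage were chosen only after the result was seen. The markers of Landsberg alleles and the splits of libraries were chosen before it.

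The lines and Col-0 differed in 157 genes for which every library of 1 background lay above 4 times the highest of the other plus 20 counts. The counted level of S30 transcripts was argued against as their source: over 182 genes chosen by this rule without ICT1-2, the log2 differences in ICT1-2_NT, where no S30 gene was counted higher, were 1.03 times those in ICT1-8098_NT (median, quartiles 0.985 to 1.1). S30 transcripts that were not counted stay open. Linkage to an insertion site was argued against: no window of 5 Mb held over 11.5% of the genes. A strain variant between the Col-0 libraries and the lines may be the source: 14 pairs of neighbouring expressed genes shared their state, where 10000 random sets of as many genes had a mean of 0.659 and at most 5. FRI was 9.86-fold higher in the lines without I3C (132 ± 7.74) than in Col_NT (13.4 ± 5.53). Landsberg-type alleles in the Col-0 libraries would give this direction, but only 1 of 3 chosen markers was measured, so this stays open. FLC, added later with no direction set, went the other way: 50.5 ± 4.99 in Col_NT, 2.02 ± 2.37 in the lines. Differences between the lines and Col-0 could therefore hold effects of background beside those of S30, and the design does not separate these.

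For groups of 3 libraries against 3, 10 splits are possible, so the share of splits as large cannot fall under 0.1. The real split gave the highest count, as 1 of 10, in each of these comparisons except Col_400 against Col_200: 6120 genes against at most 5 in the other splits for Col_200 against Col_NT, 7580 against 57 for Col_400, 524 against 44 for wounding, 2579 against 0 for ICT1-8098_NT, 4691 against 0 for ICT1-8098_200 against its own line, 4576 against 1 for ICT1-2_200 and 5510 against 1 for ICT1-2_400 against Col-0. For ICT1-8098_200 against Col_200 the real split gave 5133 and the highest other 3025. For Col_400 against Col_200, 5 of 10 splits gave as many genes as the real 26, the highest other 257, which points to a structure of these libraries other than the dose.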
